A study of Mus musculus with 6 samples.

How the data were processed

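RNA from 6 HCA-1 tumours was extracted with RNeasy columns and made into libraries with a KAPA mRNA kit, per the labels' protocols. Per the submitters' processing notes, CASAVA, FastQC, MultiQC, Trimmomatic 0.38, HISAT2 2.1.0 and featureCounts 2.0.0 were used. The genome build, the annotation release and the strand setting are not given in the sources used here, so no coordinates are printed, and reads of overlapping or antisense genes cannot be told apart. The deposited count table holds whole read counts for 55536 Ensembl genes, not normalized. A second deposited table holds a normalized signal, which per the file headers carries gene symbols, and each of its values equals the count divided by 1 constant per library (largest relative departure 5.2e-15). That table supplied the gene symbols, and of the genes with a count 1137 had none. No test used the normalized values.

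Groups came from the sample titles: Control with replicates 3, 4 and 5, and TSDP with 1, 2 and 5. Nothing in the labels names a batch, litter or sequencing day, and replicates are known as separate samples from the titles alone, so p-values measure the spread between these samples. Every pair of libraries differed beyond counting noise (chi-square per gene of 42.8 or more), so none was counted as a duplicate. No column belonged to another sample.

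Genes were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr (minimum count 10), glmQLFit and glmQLFTest with an intercept and the group, and Benjamini-Hochberg adjustment over 17423 genes at 0.05. The first fit used bias-adjusted deviances; after its results had been seen it was replaced by the legacy quasi-likelihood, the default of this version. Both called 0 genes. Standard errors are the absolute log2 fold change divided by the root of F. CPM values use TMM-scaled library sizes. The biological coefficient of variation was 34.9%. Fits with DESeq2 1.42.0 and limma 3.58.1 (voom) were alternatives. DESeq2 gave no adjusted p for 15031 genes with a count, and these stayed out of its counts.

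Gene lists were fixed before the data were examined, 37 lists with 598 genes, of which 590 were in the table and 562 were tested. When a symbol had several Ensembl IDs the one with most counts was used. Lists were tested with limma's camera (two-sided, preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the 37 lists, and with an estimated correlation and fry as alternatives. A list's score is the mean log2 CPM of its tested members. Single values per library were compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3 libraries. Correlations across the 6 libraries were tested by exact permutation without regard to group. Lists that differ between the groups can correlate for that reason alone.

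The rule for named genes was fixed before the data were examined. It took genes past the threshold, or, as none passed, the 5 with the smallest p in each direction without predicted or pseudogene-like ones. It added the member with the smallest p of each list, and in every case Nos2, Nos3, Vegfa, Cd274, Hmox1, Cd8a, Afp and Alb. Of the genes this rule took, 3 are not reported here. Genes of families with near-identical copies (Mup, Ugt2b, Iglc, Gsta, Gstm) may share reads.

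The steps were tested on 5 simulated tables of 17423 genes drawn from the means, dispersions and library sizes of this comparison, with known genes changed. For changes of 2-fold, 4-fold and 8-fold, edgeR recovered 8.36%, 76.1% and 93% of the genes, DESeq2 42.7%, 93.4% and 96.7%, and limma-voom 7.16%, 74.9% and 91.8%. False calls were 5.45%, 33.5% and 6.62% of each tool's calls. Each gene was drawn independently around its mean over all libraries, and the changed genes were taken from well-counted ones. The real libraries vary together, so these rates do not carry over to them. Alternatives were other scaling factors, other filters, other tools, the hepatocyte score as a covariate and leaving out each library.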

Results

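RNA was sequenced from liver tumours of 6 male C3H mice, 3 left untreated (Control) and 3 given TSDP. TSDP is the labels' name for a nanoparticle carrying DNIC, a nitric oxide donor, together with sorafenib, a kinase inhibitor used in advanced hepatocellular carcinoma. The tumours grew from HCA-1 cells, a mouse hepatocellular carcinoma line, of which 1000000 were placed under the liver capsule of mice 6 to 8 weeks old. TSDP was injected into a vein 6 times between day 10 and day 23, and tumours were taken on day 24. The labels do not say whether Control mice received an empty carrier. The table held 55536 genes, of which 33296 had a count. Total counts were 32533852, 32130808 and 38953397 in Control 3, 4 and 5, and 36629665, 36586150 and 36376925 in TSDP 1, 2 and 5. The question was which genes and gene groups differ between tumours with and without the treatment.

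Lists of liver and lymphocyte genes stood higher in TSDP tumours and those of hypoxia and glycolysis lower by camera, a test of whole gene lists, while 0 single genes passed the edgeR test. The hepatocyte list had a median log2 fold change of 2.84 (TSDP over Control), the B cell and plasma cell list 1.56 and the T cell list 0.63. The hypoxia list stood at -0.52 and the glycolysis list at -0.36. These list calls were made with a preset correlation between genes, and all 18 were lost when that correlation was estimated from the data. Libraries within a group differed widely: Control 3 carried almost no hepatocyte RNA.

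The share of counts in the hepatocyte list was 0.0107%, 2.1% and 0.408% in Control 3, 4 and 5, and 3.48%, 6.19% and 2.16% in TSDP 1, 2 and 5. The means were 0.839% ± 1.11 (SD, n = 3) and 3.94% ± 2.06 (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Albumin (Alb), the main plasma protein made by hepatocytes, was counted at 62.7, 10350 and 1993 CPM (counts per 1000000) in Control 3, 4 and 5, and at 17150, 32440 and 11310 CPM in TSDP 1, 2 and 5. Mitochondrial transcripts took 2.61% ± 0.198 of counts in Control and 3.55% ± 0.621 in TSDP (SD, n = 3 each, exact permutation p = 0.1). Haemoglobin genes took 0.0624% in Control 3 and at most 0.0048% in each of the others. The 10 most abundant genes took 7.55% ± 0.505 in Control and 8.45% ± 0.747 in TSDP (SD, n = 3 each, exact permutation p = 0.2). The first principal component of log2 CPM held 75.2% of the variance, with Control 3 at -148 and TSDP 2 at 94.

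**Figure D1:**
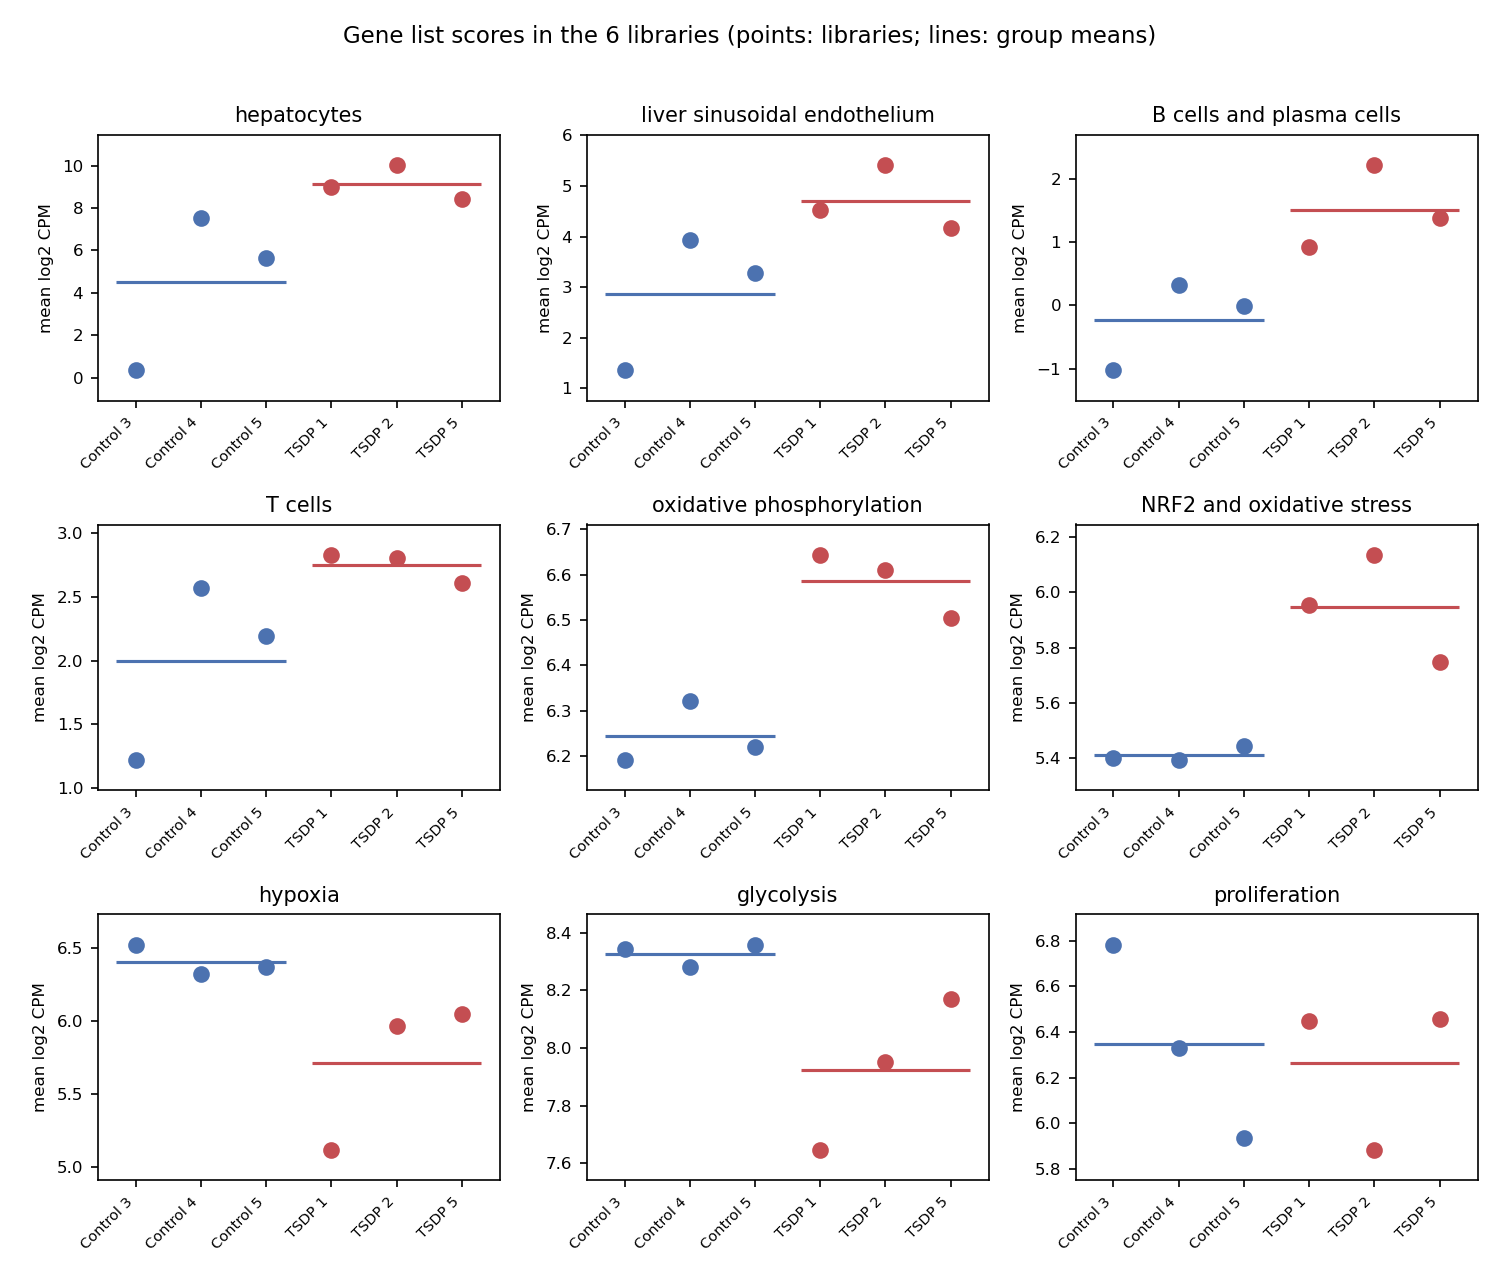
Mean log2 CPM of the tested members of 9 gene lists (y axis) in each of the 6 libraries (x axis), with blue points for Control, red points for TSDP and lines at the group means. The NRF2 score lay between 5.40 and 5.44 in Control and between 5.75 and 6.13 in TSDP, while the hepatocyte score of Control 3 was 0.36 and those of the other libraries 5.64 or more.

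Of 17423 genes tested with edgeR's quasi-likelihood F test, 0 were higher and 0 lower in TSDP at a Benjamini-Hochberg adjusted p under 0.05, and so 0 in each direction at a change of 2-fold or more. At an unadjusted p under 0.05 there were 2326 genes, 1499 higher and 827 lower. Of the 10 splits of the 6 libraries into 3 and 3, 2 gave as many, the real one included: the split of Control 3, Control 5 and TSDP 5 against the others gave 2443, and the other false splits 113 to 990. The smallest adjusted p was 0.326. limma-voom also called 0 genes, with 2646 at an unadjusted p under 0.05. DESeq2 called 548 higher and 73 lower, of which 427 and 20 changed by 2-fold or more. In simulated tables with each gene drawn independently DESeq2's calls held 33.5% false ones and edgeR's 5.45%. The real libraries varied along a shared axis, so these rates do not carry over to the calls made here. Nor do the 0 edgeR calls show that large changes were absent. The 3 Control and 3 TSDP values did not overlap for 2273 genes higher in TSDP and 1526 lower, 21.8% of those tested. By chance alone 10% would be without overlap, but genes vary together here, so the excess was not tested.

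The genes with the smallest p, none past the threshold, are given as values. Etnppl (ENSMUSG00000019232), a phospho-lyase of phosphoethanolamine found in liver and astrocytes, averaged 0.554 CPM ± 0.374 in Control and 37.8 CPM ± 9.78 in TSDP (SD, n = 3 each), a log2 fold change of 6.06 ± 0.59 (SE) with an edgeR adjusted p of 0.326. Enpp6 (ENSMUSG00000038173), a choline-releasing phosphodiesterase, averaged 0.239 and 1.31 CPM. Mup21 averaged 0.687 and 59.3 CPM and Iglc1, an immunoglobulin light chain segment, 0.0575 and 2.06 CPM. Ugt2b38 had 0, 0 and 0.0249 CPM in Control and 2.41, 2.02 and 0.725 CPM in TSDP. Reads of Mup21, Iglc1 and Ugt2b38 can be shared with near-identical family members, so their values are uncertain. Tef (ENSMUSG00000022389) and Dbp (ENSMUSG00000059824), related transcription factors driven by the circadian clock, had log2 fold changes of -1.12 ± 0.15 and -1.90 ± 0.31 (SE). Tef averaged 52.3 CPM in Control and 24.1 CPM in TSDP, and Dbp 9.57 and 2.56 CPM. Crebrf averaged 105.7 and 64.5 CPM, and the olfactory receptor gene Olfr1029 5.47 and 2.19 CPM. Without the filter on low counts Etnppl was the 1 gene called, with an edgeR adjusted p of 0.0462.

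**Figure D2:**
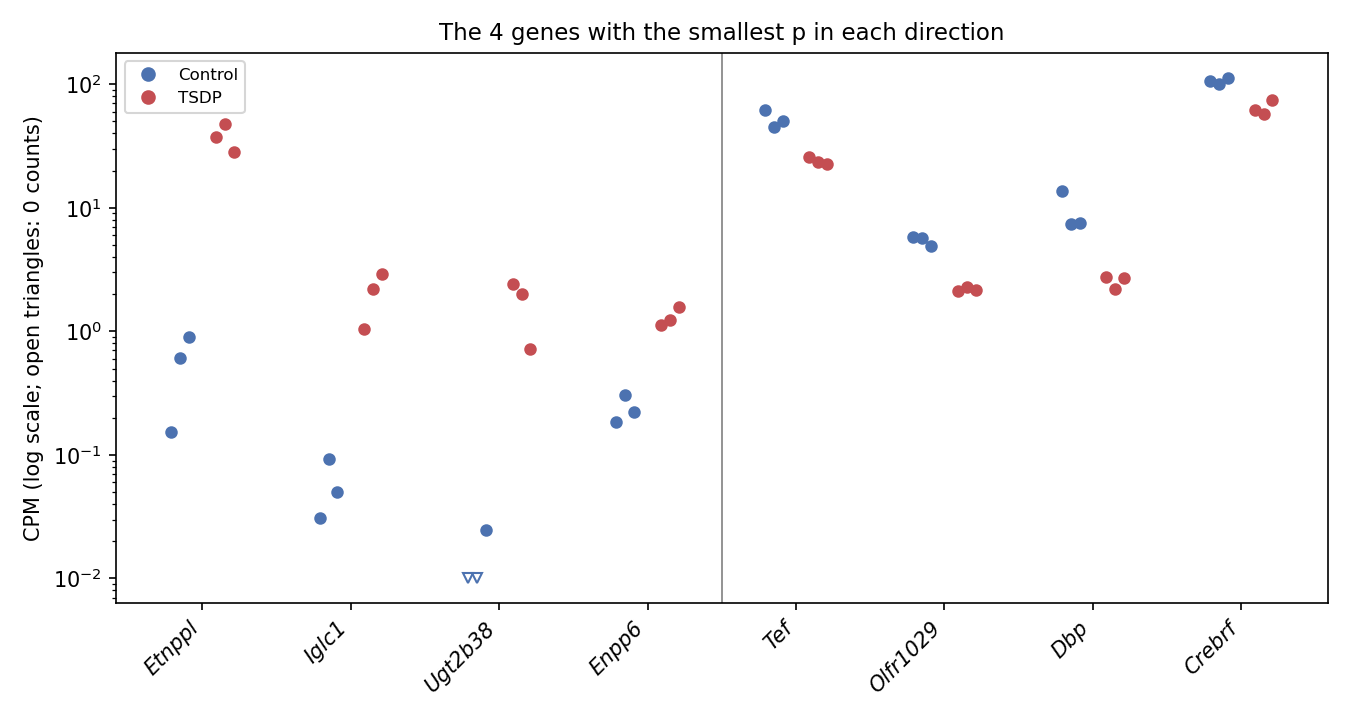
CPM on a log axis (y axis) of the 4 genes with the smallest p in each direction (x axis), with 1 point per library, blue for Control and red for TSDP, and open triangles at the foot of the axis for libraries with 0 counts. Etnppl lay between 0.154 and 0.895 CPM in Control and between 28.1 and 47.7 CPM in TSDP, and Tef between 44.9 and 61.9 and between 22.8 and 25.9 CPM.

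Genes of liver tissue had the largest median among the lists past the threshold. All 22 tested members of the hepatocyte list had positive log2 fold changes, with 0 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 1.12e-08, and adjusted p = 0.582 with an estimated correlation). Mup20, a major urinary protein whose reads can be shared with its relatives, averaged 3.92 CPM in Control and 139 CPM in TSDP. Alb had a log2 fold change of 2.30 ± 1.46 (SE, edgeR adjusted p = 0.514). The list of liver sinusoidal endothelium had a median of 1.78, with 11 of 11 members positive (camera adjusted p = 0.000785, and adjusted p = 0.582 with an estimated correlation). Its member Oit3 averaged 5.58 and 22.5 CPM. Kupffer cell genes had a median of 1.31 with 8 of 10 positive (camera adjusted p = 0.0104, and adjusted p = 0.582 with an estimated correlation). Nr1h3, the LXR-alpha receptor, averaged 12.6 and 29.2 CPM. The Kupffer call was lost without TSDP 2 (camera adjusted p = 0.0552). Wnt and beta-catenin targets had a median of 1.20 with 12 of 13 positive (camera adjusted p = 0.000232), and drug transporters and metabolism 1.44 with 10 of 14 positive (camera adjusted p = 0.0125), both with adjusted p = 0.582 with an estimated correlation. Among the members of these lists Oat, an ornithine aminotransferase, averaged 32.8 and 93.0 CPM, and Abcg2, a drug efflux pump, 21.0 and 42.4 CPM. These calls were lost with the hepatocyte score as a covariate, at camera adjusted p of 0.798 for the sinusoidal and Kupffer lists, 0.403 for Wnt and 0.682 for drug transporters. Of the sinusoidal, Kupffer, Wnt and drug lists, 0 members passed over all genes and 0 adjusted over the list alone. Across the 6 libraries the hepatocyte score correlated with the sinusoidal score at r = 0.987 (exact permutation p = 0.00139) and rho = 1 (p = 0.00278), and with the Wnt score at r = 0.970 (p = 0.00278) and rho = 0.943 (p = 0.0167). Without Control 3 and Control 5, the libraries farthest from the median hepatocyte score, r was 0.967 and 0.914. With the Benjamini-Hochberg adjustment over 12 relations, the p-values of r were 0.00667 for both and those of rho 0.0167 and 0.02.

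Lymphocyte lists stood higher in TSDP, and most of these calls turned or were lost with the hepatocyte score as a covariate. In the B cell and plasma cell list 12 of 13 tested members were positive, with 0 past the threshold over all genes and 9 adjusted over the list alone (camera adjusted p = 1.67e-07, and adjusted p = 0.582 with an estimated correlation). In the T cell list 19 of 20 were positive, with 0 adjusted over the list alone (camera adjusted p = 5.8e-05, and adjusted p = 0.582 with an estimated correlation). Cd8a, the marker of cytotoxic T cells, averaged 14.0 CPM ± 5.81 and 18.8 CPM ± 0.8 (SD, n = 3 each, edgeR adjusted p = 0.58), and Ubash3a 1.45 and 2.50 CPM. The cytotoxic lymphocyte list had a median of 0.51 (camera adjusted p = 0.000718, and adjusted p = 0.645 with an estimated correlation), with Gzma, a granzyme, at 0.505 and 1.64 CPM. Immune checkpoint and regulatory T cell genes had a median of 0.32 (camera adjusted p = 0.0412, and adjusted p = 0.725 with an estimated correlation), with Foxp3, the regulatory T cell factor, at 1.26 and 3.27 CPM. Cd274, which encodes PD-L1, averaged 64.7 and 66.2 CPM. Dendritic cell genes had a median of 0.66 with 15 of 15 positive (camera adjusted p = 5.36e-05, and adjusted p = 0.582 with an estimated correlation), with Cd209a at 1.12 and 3.97 CPM. Genes of MHC class II presentation had a median of 0.45 with 12 of 12 positive (camera adjusted p = 0.00686, and adjusted p = 0.721 with an estimated correlation), with Ctss, the protease cathepsin S, at 472 and 608 CPM. The interferon gamma list had a median of 0.20 (camera adjusted p = 0.0299, and adjusted p = 0.832 with an estimated correlation), with the chemokine Cxcl9 at 67.8 and 140.1 CPM. In the cytotoxic, checkpoint, dendritic, class II and interferon gamma lists 0 members passed over all genes and 0 adjusted over the list alone.

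With the hepatocyte score as a covariate the B cell and plasma cell list stayed higher (camera adjusted p = 0.000323), while the direction turned to lower for T cells (0.125), dendritic cells (0.396), cytotoxic lymphocytes (0.0213), checkpoints (0.0139), class II presentation (6.16e-05) and interferon gamma (2.24e-12), the last 4 past the threshold as lower. These covariate calls were made at the preset correlation alone. Without the covariate the estimated correlation between genes was 0.937 in the interferon gamma list and 0.897 in class II presentation, against the preset 0.01. Several of the immune calls made without the covariate rested on 1 library. Without Control 3 the camera adjusted p was 0.131 for cytotoxic lymphocytes, 0.184 for checkpoints and for class II presentation, and 0.118 for the interferon gamma list, whose direction turned to lower. Without TSDP 2 it was 0.0793 for checkpoints and 0.0667 for interferon gamma, and without TSDP 5 it was 0.0799 and 0.0675. The hepatocyte score correlated across the 6 libraries with the T cell score at r = 0.992 (exact permutation p = 0.00278, adjusted 0.00667) and rho = 0.943 (p = 0.0167, adjusted 0.02), and with the B cell score at r = 0.915 (p = 0.00278, adjusted 0.00667) and the same rho and p. Without Control 3 and Control 5, r was 0.862 and 0.888. The dendritic, cytotoxic and Kupffer scores correlated with it at r = 0.998, 0.979 and 0.945 (adjusted p = 0.00667, 0.00715 and 0.00715), or 0.98, 0.814 and 0.846 without those libraries. Both groups entered each of these correlations, so they do not show a tie to liver content apart from treatment.

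Hypoxia and glycolysis genes stood lower in TSDP. All 17 tested members of the hypoxia list had negative log2 fold changes, with 0 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 4.38e-06, and adjusted p = 0.582 with an estimated correlation). Kdm3a, a histone demethylase induced by HIF, averaged 157.5 CPM ± 19.2 in Control and 102.4 CPM ± 14.9 in TSDP (SD, n = 3 each). Vegfa, the vascular growth factor, averaged 361 and 255 CPM, a log2 fold change of -0.50 ± 0.22 (SE, edgeR adjusted p = 0.384). In the glycolysis list 14 of 15 members were negative, with 0 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 4.14e-05, and adjusted p = 0.582 with an estimated correlation). Gpi1, glucose-6-phosphate isomerase, averaged 608 CPM ± 14.4 in Control and 389 CPM ± 105.2 in TSDP. The hypoxia score lay between 6.32 and 6.52 in Control and was 5.12, 5.97 and 6.05 in TSDP 1, 2 and 5. Both lists stayed lower with the hepatocyte score as a covariate at the preset correlation (camera adjusted p = 0.000516 for hypoxia and 0.00191 for glycolysis). Across the 6 libraries the hepatocyte score correlated with the hypoxia score at r = -0.628 (exact permutation p = 0.188, adjusted 0.205) and rho = -0.943 (p = 0.0167, adjusted 0.02), and with the glycolysis score at r = -0.638 (p = 0.165, adjusted 0.198) and rho = -0.886 (p = 0.0333, adjusted 0.0363). Without Control 3 and Control 5, r was -0.422 and -0.634.

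Genes of oxidative phosphorylation and of the NRF2 response stood higher. In the first list 18 of 18 members were positive with a median of 0.30, and 0 passed over all genes and 6 adjusted over the list alone (camera adjusted p = 7.17e-07, and adjusted p = 0.582 with an estimated correlation). Ndufa4, a respiratory chain subunit, averaged 50.6 and 90.5 CPM. In the NRF2 list 15 of 18 were positive with a median of 0.34, and 0 passed over all genes and 7 adjusted over the list alone (camera adjusted p = 0.000112, and adjusted p = 0.582 with an estimated correlation). Gstm1, a glutathione transferase, averaged 107 CPM ± 10.2 in Control and 292 CPM ± 107.4 in TSDP. Hmox1, which encodes heme oxygenase 1, averaged 58.8 and 55.3 CPM, a log2 fold change of -0.09 ± 0.33 (SE, edgeR adjusted p = 0.92). Several members, glutathione transferases among them, are also abundant in liver. Both lists stayed higher with the hepatocyte score as a covariate at the preset correlation (camera adjusted p = 7.08e-05 for oxidative phosphorylation and 8.03e-06 for NRF2). The hepatocyte score correlated with the oxidative phosphorylation score at r = 0.833 (exact permutation p = 0.00556, adjusted 0.00834) and rho = 0.943 (p = 0.0167, adjusted 0.02), and with the NRF2 score at r = 0.729 (p = 0.0653, adjusted 0.0871) and rho = 0.829 (p = 0.0583, adjusted 0.0583). Without Control 3 and Control 5, r was 0.872 and 0.981.

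Genes of nitric oxide synthesis and signalling had a median of 0.61 with 13 of 17 positive, 0 past the threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00092, and adjusted p = 0.582 with an estimated correlation). This call was lost with the hepatocyte score as a covariate (camera adjusted p = 0.125). The list holds genes that hepatocytes express. Its member Ass1, also on the list of periportal hepatocyte genes below, averaged 73.1 CPM in Control and 367 CPM in TSDP. Ddah1, which breaks down an inhibitor of nitric oxide synthases, averaged 7.18 and 20.9 CPM. The synthases themselves, Nos2 and Nos3, averaged 14.3 CPM ± 4.04 and 10.1 CPM ± 9.01, and 5.09 CPM ± 0.353 and 6.97 CPM ± 0.961, in Control and TSDP (SD, n = 3 each), with edgeR adjusted p of 0.74 and 0.372. Endothelial and angiogenesis genes had a median of 0.46 with 16 of 20 positive, and 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000718, and adjusted p = 0.582 with an estimated correlation). Mmrn2, an endothelial matrix protein, averaged 10.2 and 18.2 CPM. The endothelial list stayed higher with the covariate at the preset correlation (camera adjusted p = 0.000504). Its score correlated with the hepatocyte score at r = 0.571 (exact permutation p = 0.232, adjusted 0.232) and rho = 0.943 (p = 0.0167, adjusted 0.02), with r = 0.901 without Control 3 and Control 5.

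**Figure D3:**
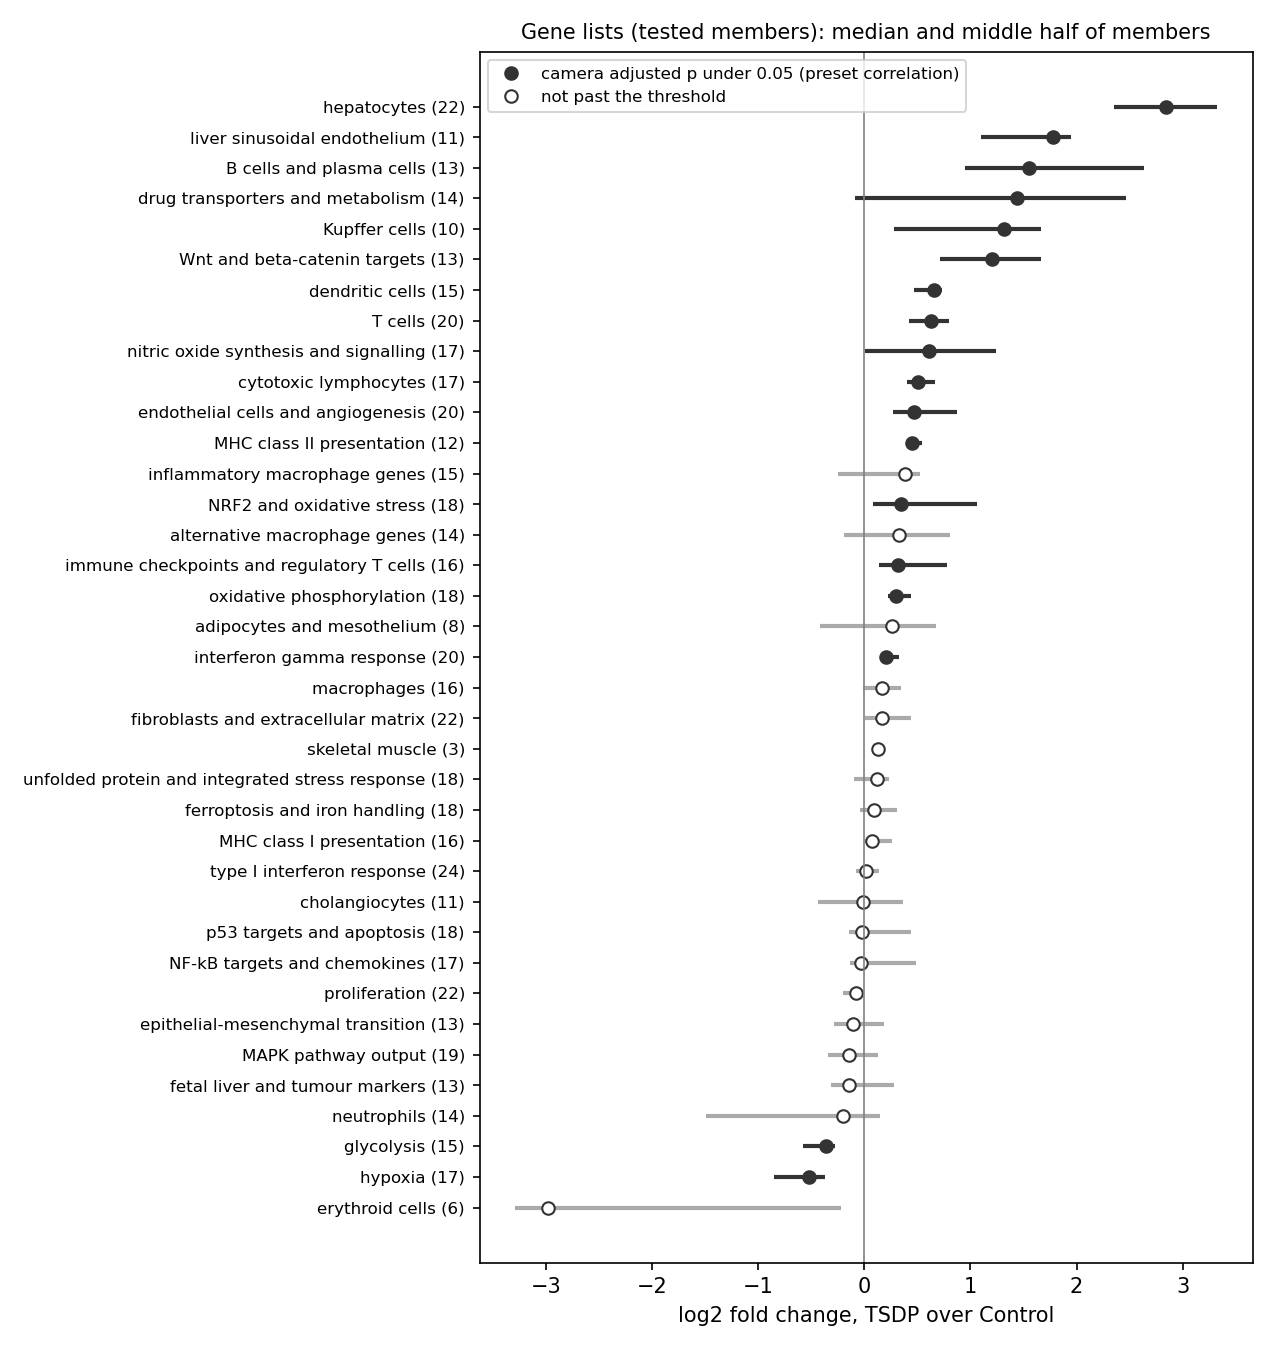
Median log2 fold change, TSDP over Control (x axis), of the tested members of 37 gene lists (y axis, number tested in brackets), with bars over the middle 50% of members and filled points for camera calls at the preset correlation. The hepatocyte list had the largest median, 2.84, and the erythroid list, not past the threshold, the lowest, -2.98. The erythroid score was 4.48 in Control 3 and 1.86 or less in each of the other libraries.

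The other 19 lists did not pass. Proliferation genes had a median of -0.08 (camera adjusted p = 0.397), with E2f1 at 27.7 and 22.7 CPM, and genes of MAPK output, the pathway that sorafenib inhibits at RAF, -0.14 (0.25), with Spred3 at 24.4 and 18.3 CPM. Type I interferon genes had a median of 0.02 (0.583), MHC class I presentation 0.07 (0.21), macrophages 0.17 (0.21), inflammatory macrophage genes 0.38 (0.397) and alternative macrophage genes 0.32 (0.249). Neutrophil genes had a median of -0.20 (0.21), with S100a8 at 5.99 and 2.13 CPM; this list passed as lower without Control 3 (0.00242) and without TSDP 2 (0.028). Other lists passed with 1 library left out: without Control 4 macrophages (0.0164), class I presentation (0.0139) and cholangiocytes (0.0181) as higher and MAPK output (0.024) as lower, without Control 5 proliferation (0.00282) as lower and inflammatory macrophage genes (0.0418), p53 targets (0.0306) and the unfolded protein response (0.0391) as higher, and without TSDP 5 fibroblasts (0.0327) as higher. With the hepatocyte score as a covariate, at the preset correlation, proliferation (0.000149) and erythroid cells (0.0171) passed as higher. In that setting neutrophils (0.0101), class I presentation (0.000149), type I interferon (1.27e-05) and cholangiocytes (0.000894) passed as lower. With an estimated correlation, fitted without the covariate, 0 lists passed with or without Control 3. Fibroblast and matrix genes had a median of 0.16 (0.354), the ferroptosis and iron list 0.09 (0.21), the unfolded protein and stress response 0.11 (0.354), skeletal muscle 0.13 (0.397), adipocytes and mesothelium 0.26 (0.583) and erythroid cells -2.98 (0.854). The erythroid score was 4.48, 1.86 and 0.13 in Control 3, 4 and 5 and 1.47, 1.70 and 1.38 in TSDP 1, 2 and 5. Without Control 3 its direction turned to higher (0.175). Fetal liver and tumour markers had a median of -0.15 (0.854), with Afp, the fetal protein raised in many hepatocellular carcinomas, at 3.52 and 6.40 CPM. In 4 lists the signs differed: for cholangiocytes the median was -0.01 and the mean -0.03, for NF-kB targets -0.03 and 0.17, for p53 targets -0.02 and 0.12, and for epithelial-mesenchymal transition -0.10 and 0.02, while camera gave the direction higher for each (adjusted p of 0.38, 0.397, 0.583 and 0.818). The members with the smallest p in these lists, none past the threshold, included Apoe, an apolipoprotein of macrophages and hepatocytes, at 753 CPM in Control and 3274 CPM in TSDP, Cdh1, which encodes E-cadherin, at 37.6 and 72.1 CPM, and Sod2, mitochondrial superoxide dismutase, at 42.6 and 67.9 CPM. Herpud1 averaged 65.1 and 136.7 CPM, Acta2 56.1 and 104.1 CPM, Btg2 43.9 and 68.8 CPM, Mgl2 38.0 and 70.4 CPM, Erap1 94.3 and 121 CPM, and Aco1 68.6 and 91.9 CPM. Mx2 averaged 6.04 and 10.5 CPM, Ccl3 6.42 and 4.71 CPM, Fabp4 36.3 and 45.7 CPM, Klf1 0.175 and 0.355 CPM, and Tnni2 0.646 and 0.776 CPM.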

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

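Alternatives chosen after seeing the data were DESeq2 without Control 3, DESeq2 with the hepatocyte covariate, limma-voom with sample quality weights, and camera with an estimated correlation without Control 3. The legacy setting of the edgeR fit was also chosen after results had been seen, in place of bias-adjusted deviances, the first fit, which is given here as an alternative. No paired analysis was possible because the groups share only replicate number 5. Counts of genes stayed at 0 in each direction with DESeq2 size factors, upper-quartile factors, limma-voom with or without quality weights, a CPM filter, the hepatocyte covariate, bias-adjusted deviances and each library left out. Without a filter on low counts edgeR called 1 gene, higher and over 2-fold. DESeq2 called 548 higher and 73 lower (427 and 20 at 2-fold), 494 and 65 without Control 3 (456 and 55), and 33 and 111 with the hepatocyte covariate (32 and 104); the cause was not tested. All 10 splits of the 6 libraries into 3 and 3 gave as many edgeR genes (10 at 2-fold too) as the real split, 0, with 0 in the highest other. For DESeq2, 1 split gave as many as the real 621, the highest other giving 142. For camera lists, 6 splits gave as many as the real 18, the highest other giving 21. With 10 splits no share under 0.05 can be had. Lists past the threshold were 0 higher and 0 lower with an estimated correlation, with or without Control 3, and 0 and 0 with fry, whose smallest adjusted p was 0.0726 and which had 6 lists at an unadjusted p under 0.05. The estimated-correlation test had 1. Leaving out 1 library gave 12 to 19 higher and 2 to 3 lower. With the hepatocyte covariate, run at the preset correlation alone, there were 6 higher (B and plasma cells, oxidative phosphorylation, endothelial cells, NRF2, proliferation and erythroid cells) and 10 lower. Directions reversed there, with these adjusted p: T cells and hepatocytes 0.125, cytotoxic lymphocytes 0.0213, checkpoints 0.0139, inflammatory macrophage genes 0.578, dendritic cells 0.396, class I 0.000149, class II 6.16e-05, type I interferon 1.27e-05, interferon gamma 2.24e-12, NF-kB and p53 0.403, fibroblasts 0.145, MAPK 0.442, proliferation 0.000149, cholangiocytes 0.000894, erythroid cells 0.0171, skeletal muscle 0.754, and adipocytes 0.798; the cause was not tested, and the hepatocyte list's members also define the covariate. With an estimated correlation and without Control 3, reversals had adjusted p of 0.885 (class I, type I interferon, proliferation, erythroid cells), 0.79 (interferon gamma), 0.904 (p53) and 0.922 (cholangiocytes). With 1 library left out, camera adjusted p ranged, for lists that reversed at least once, from 0.0164 to 0.91 (macrophages), 0.0139 to 0.446 (class I), 0.0638 to 0.55 (type I interferon), 8e-04 to 0.118 (interferon gamma), 0.0327 to 0.952 (fibroblasts), 0.735 to 0.913 (epithelial-mesenchymal transition), 0.024 to 0.989 (MAPK), 0.00282 to 0.388 (proliferation), 0.0306 to 0.919 (p53), 0.618 to 0.956 (fetal liver), 0.0181 to 0.773 (cholangiocytes), 0.104 to 0.981 (erythroid cells) and 0.0636 to 0.971 (adipocytes). Of the 54 named genes 6 changed sign somewhere. With the hepatocyte covariate log2 fold changes were 0.17 for E2f1, -0.14 for Tnni2, -0.67 for Cd274, 0.37 for Hmox1, -0.32 for Cd8a and -0.61 for Alb in edgeR, and 0.17, -0.14, -0.67, 0.36, -0.32 and -0.61 in DESeq2. Cd274 was -0.042 with upper-quartile factors, -0.23 with quality weights and -0.26 in DESeq2 without Control 3, where Hmox1 was 0.20. With 1 library left out Cd274 ranged from -0.26 to 0.30 and Hmox1 from -0.41 to 0.21. DESeq2 put 25 of the 54 genes past the threshold. Shares of counts kept their direction without mitochondrial genes.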

Other observations

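The gene groups and tests here were chosen after the values were seen. For the liver zone the prediction was written before its test, but on these same gene groups. Genes that growth hormone holds higher in male mouse liver stood apart between the groups: 12 of 12 tested members had positive log2 fold changes, 11 without overlap between the groups, with a median of 2.97, beside 17 of 22 hepatocyte genes, 8 of 9 periportal genes and 6 of 8 pericentral genes without overlap, and 21.8% of all genes tested. Elovl3, a fatty acid elongase, averaged 1.16 CPM in Control and 52.9 CPM in TSDP, and Slco1a1, an organic anion transporter, 7.01 and 109.4 CPM, with edgeR adjusted p of 0.326 and 0.356. Between Control 4 and TSDP 5, single libraries where albumin was alike at 10350 and 11310 CPM, Egfr was the only tested member that was lower (239 and 141.2 CPM). Serpina1e (2035 and 2420 CPM) and C8a (223.4 and 234.3 CPM) were nearly level. The rest were higher by varying amounts, such as Slco1a1 (16.0 and 63.0 CPM), Cyp2d9 (59.3 and 103.9 CPM) and Elovl3 (2.12 and 30.9 CPM). Periportal genes had a median of 2.33 with 9 of 9 positive and pericentral genes 2.23 with 8 of 8. With all 6 libraries the periportal minus pericentral score differed by -0.04, and the groups overlapped. Without Control 3 that score was -0.87 ± 0.11 in Control 4 and 5 (SD). In TSDP it was -0.45 ± 0.17 (SD, n = 3), a difference of 0.43 with no overlap (exact permutation p = 0.1). Acute-phase proteins had 7 positive and 5 negative members. The log2 ratio of their summed CPM to that of hepatocyte genes was -1.42 ± 0.72 in Control and -2.46 ± 0.12 in TSDP (SD, n = 3 each, no overlap, exact permutation p = 0.1). It was -1.21, -0.84 and -2.22 in Control 3, 4 and 5, and -2.53, -2.32 and -2.53 in TSDP 1, 2 and 5. Control 3 had 0.0107% of counts in hepatocyte genes, so its ratio says little about liver tissue, and Control 5 lay close to TSDP 2. Saa1, a serum amyloid, stood at 570 CPM in Control 4 and between 0.278 and 100.2 CPM in the other libraries. Xist was counted at 3.35 to 33.3 CPM in the 6 libraries, beside the Y-linked Ddx3y at 114.8 to 192.5 CPM.

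The lymphocyte and hypoxia patterns were set against a different share of liver tissue in the samples. With the hepatocyte score as a covariate the difference in T cell score went from 0.75 (0.36 without Control 3) to -0.10 ± 0.10 (SE, 3 residual degrees of freedom) and that in B cell score from 1.75 to 0.79 ± 0.53 (0.45 without Control 3), while with the hepatocyte percentage on a linear scale T cells went from 0.425 to 0.187 ± 0.256 and B cells from 1.009 to 0.191 ± 0.388 relative units. The hypoxia score went from -0.69 to -0.58 ± 0.50 and the glycolysis score from -0.40 to -0.36 ± 0.25, but much of this came from TSDP 1, without which hypoxia went from -0.40 to -0.26 and glycolysis from -0.27 to -0.21; the linear values went from -0.418 to -0.413 ± 0.247 and from -0.261 to -0.206 ± 0.15, and the list calls stayed past the threshold with the covariate (camera adjusted p = 0.000516 and 0.00191 at the preset correlation). None of these adjusted differences exceeded 3.18 times its SE, and against proliferation genes, which a larger liver share would lower at least as far, hypoxia differed by -0.61 ± 0.46 (SE; -0.22 without TSDP 1, -0.92 without TSDP 2) and glycolysis by -0.32 ± 0.35 (SE; -0.09 without TSDP 1, -0.10 without Control 5, -0.53 without Control 3, -0.52 without TSDP 2), within 2.78 times the SE. The hepatocyte share itself separates the groups, so for these lists a share of liver tissue and an effect of TSDP both remain open, the effect as untested.

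Another pattern was the idea that male-biased liver genes stood higher in TSDP even relative to hepatocyte genes, and no test here decides it for the list as a whole. The log2 ratio of summed male-biased to summed hepatocyte CPM differed by -0.63 ± 0.82 (SE), and by -0.55 ± 0.19 with the periportal minus pericentral score as a covariate for another zone of the lobule, but Serpina1e, at 4424 CPM in TSDP, sets the sum in most libraries and Egfr, at 56.6 CPM, in Control 3, so these values say nothing about genes such as Elovl3; without Control 3 the ratio was -3.02 ± 0.06 in Control (SD, n = 2) and -2.83 ± 0.04 in TSDP (SD, n = 3), a difference of 0.19 with no overlap (exact permutation p = 0.1). With the genes weighed alike, the male-biased minus hepatocyte score was -3.24 ± 0.35 and -3.18 ± 0.09 in those 5 libraries, a difference of 0.06 with overlap (exact permutation p = 0.8), whereas with the hepatocyte score as a covariate the male-biased score differed by 0.74 ± 0.13 (SE), beyond 3.18 times its SE, and on a linear scale by 0.251 ± 0.173 relative units, within it. DESeq2 with the hepatocyte covariate gave 7 positive and 5 negative members with a median of 0.28 and called 2 of the 12, Elovl3 (2.80, adjusted p = 0.000931) and Ugt2b1 (1.30, adjusted p = 0.00673), and outside the list Mup21 (4.33, adjusted p = 2.58e-13) and Etnppl (4.82, adjusted p = 5.95e-22), which were among the genes with the smallest p. The hepatocyte list, the reference or covariate in these tests, itself holds the major urinary protein genes Mup3 and Mup20. Their log2 fold changes of 5.22 and 5.14 lie above its median of 2.84. They raise the hepatocyte score in TSDP and can hide a difference. A share of liver tissue, a zone and a change of growth hormone action with treatment all stay open.

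The last pattern was lower expression of clock genes of the Dbp phase, with 10 of 10 tested members negative and a median of -0.98. Of these 10, 5 were without overlap between the groups, beside 21.8% of all genes tested, and Usp2 was nearly level at -0.04. Scores were 4.76 ± 0.21 in Control and 3.84 ± 0.08 in TSDP (SD, n = 3 each, exact permutation p = 0.1). A larger share of liver would lower no gene further than those that liver hardly expresses, such as proliferation genes. The Dbp-phase minus proliferation score was -1.59 ± 0.29 in Control and -2.43 ± 0.25 in TSDP (SD, n = 3 each). The difference of -0.83 ± 0.22 (SE) was beyond 2.78 times its SE and between -0.98 and -0.67 with 1 library left out. If proliferation in the tumour itself was alike in both groups, this argues against a liver share as the whole cause. That condition was not tested, and proliferation genes turned to higher with the hepatocyte covariate (camera adjusted p = 0.000149 at the preset correlation). The Dbp-phase list was drawn up after Tef and Dbp were seen and holds both. The test against proliferation genes took the place of the covariate comparison, which had left the question open, after that result was seen. With the hepatocyte score as a covariate the difference of -0.92 became -0.64 ± 0.04 (SE) and DESeq2 called Tef (-0.82, adjusted p = 0.0145) and Dbp (-1.21, adjusted p = 0.0191), while with the hepatocyte percentage on a linear scale -0.617 became -0.496 ± 0.193 relative units, within 3.18 times its SE. Genes of the opposite phase differed by 0.72, or 0.25 ± 0.13 (SE; 0.15 without Control 3, 0.16 without Control 4) with the hepatocyte score as a covariate, with log2 fold changes of 1.66 for Npas2 and 0.68 for Nfil3 but -0.06 for Clock and 0.26 for Arntl, which decides neither way on another time of day at tissue collection. The labels give no hour of sampling, so time of day and treatment may each have contributed.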
